A study of Mus musculus with 23 samples.

How the data were processed

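Primary mouse embryonic fibroblasts from embryonic day 14.5, were starved for 48 hours in 1% serum and then kept for 2 hours with 200 µM 4-thiouridine in either 1% serum (starved) or 10% serum (treated). The labels give their background as C57/BLACK6 and ATF1 -/+. 4-thiouridine is a uridine analogue that cells build into the RNA they make, so that RNA made during those 2 hours carries a thiol group. Per the labels' protocols, thiolated RNA was captured on an organomercurial matrix and is called newly transcribed RNA here. The other 2 kinds of RNA were total RNA and amplified total RNA. The label protocol of all samples speaks of a linear amplification, so the titles alone tell total from amplified total RNA. Samples were grouped by their titles into 6 groups, of which 5 held 4 arrays and the amplified starved group held 3. The titles number the arrays as biological replicates.

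The deposited values were 1 linear signal intensity per Affymetrix probe set and array, for 12488 probe sets on 23 arrays, from 0 to 11017.1 in steps of 0.1, with 42 values at 0. Per the labels, each array was hybridised after reverse transcription, linear amplification and T7 labelling with biotin. The software that summarised the probes, and any scaling, were not given in the sources used here. No pair of arrays held identical values. Median raw intensities per array ran from 7.3 to 75.2, a span of 1.97 on the log2(value + 16) scale, above the limit of 0.5 at which quantile normalization was to be applied. Arrays were therefore quantile normalized and log2(value + 16) was taken. Fold changes are on that scale, which understates the change of dim probe sets. The 66 control probe sets were left out of all tests, which leaves 12422. The precision is limited by the number of arrays.

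Gene names came from a table of the platform's annotation. In it 10833 of the tested probe sets had 1 gene symbol (8251 genes), 396 had several and 1193 were not listed, and only those with 1 symbol were named. Symbols were compared through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, which changed 0 of them; no coordinates were used. Where a gene had several probe sets, the brightest over all arrays stood for it. The labels give the genotype at Atf1, whose probe set lists several genes, so no value is given for it.

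Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over 12422 probe sets, and a probe set was called at an adjusted p below 0.05. There were 8 comparisons. The first were the serum response (treated minus starved) in each of the 3 kinds of RNA. Others were the difference of the responses between newly transcribed and amplified total RNA and between newly transcribed and total RNA, newly transcribed against amplified total RNA in each serum condition, and amplified against unamplified total RNA. Each was fitted on the arrays of the kinds it compares, without a block. Values are log2 differences ± the SE of the fit unless stated otherwise. Comparisons, tests, gene lists, the rule for named genes and most other settings to be tried were fixed before the data were examined.

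The replicate numbers in the titles were checked as pairs by correlating, over all probe sets, the deviations of same-numbered arrays from their group means; a comparison was taken as paired where every pair exceeded 0.1. Newly transcribed starved and treated arrays paired (0.80, 0.80, 0.76 and 0.70), and so did those of total RNA (0.70, 0.23, 0.47 and 0.57), with every array closest to the one of its own number. Newly transcribed and amplified treated arrays also paired (0.56 to 0.73). For these comparisons a fit with the replicate number as a block is given beside the one without it. The pairing comes from the data, and the titles do not say what a number shares.

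There were 24 gene lists. They covered immediate early transcription factors (23 genes measured), targets of serum response factor (SRF) and the actin cytoskeleton (27), feedback regulators of signalling (20), secreted growth factors, cytokines and proteases (29), SMAD and ID genes (14), growth arrest and starvation genes (26), and cholesterol and fatty acid synthesis (20). Others covered G1 cyclins and S phase (23), G2 and mitosis (19), ribosome biogenesis and MYC targets (25), mRNA decay regulators (19), circadian genes (14), extracellular matrix (27), and ribosomal proteins (16). The rest were oxidative phosphorylation (30), glycolysis (11), p53 and amino acid stress targets (17) and interferon response (17). Marker lists of other cell types covered macrophages (14), endothelium (9), epithelium (11), skeletal muscle (13), neurons and glia (12) and erythroid cells (6). Some genes are in more than 1 list. Each list was tested with camera against all other genes with 1 symbol, each by its brightest probe set. The preset correlation was 0.01, with adjustment over the 24 lists, and the test was repeated with an estimated correlation.

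Named genes were, among probe sets with 1 symbol past the threshold whose groups did not overlap, the 8 with the largest rise and the 8 with the largest fall; the 4 members of each described list with the largest absolute change; and Fos, Jun, Egr1, Myc and Actb in the serum responses. Alternatives were values as deposited, arrays scaled to 1 median, a pseudocount of 1 or 64, removal of the dimmest 25% or 50% of probe sets, and array weights. Others were all 23 arrays in 1 fit, trend and robust variance, a further limit of 2-fold, other rules for several probe sets per gene, the replicate block, the culture as a random block, total in place of amplified total RNA, and leaving out each array. Fits by array cluster, the alternatives with the block kept and correlations of responses from 2 numbers each were chosen after seeing the data. The steps were tested on simulated data with 100 probe sets changed 2-fold and 100 changed 4-fold. For newly transcribed RNA the serum test found 19 and 63 of them without pairs and 63 and 97 with pairs. For total RNA it found 48 and 93 without pairs and 76 and 95 with pairs, and for amplified total RNA it found 0 and 31. False calls numbered 0 to 7 over all fits. The simulated noise was independent between probe sets, and the paired fits were given the same blocks that had been simulated. These counts therefore do not bound the false calls on the real arrays, whose probe sets vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.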

Results

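The 23 arrays measured RNA of mouse embryonic fibroblasts, primary connective tissue cells, 2 hours after serum-starved cultures were given 10% serum or kept in 1% serum. There were 3 kinds of RNA: newly transcribed RNA (4 arrays per serum condition), total RNA (4 per condition) and amplified total RNA (3 starved, 4 treated). The design asks which early changes come from synthesis and which from turnover, and whether changes of scarce transcripts can be seen at the level of transcription. Median raw signals per array ran from 24.2 to 72.05 in newly transcribed, 20 to 54.2 in total and from 7.3 upwards in amplified total RNA. With values as deposited, to which no scaling was applied here, the median change of all probe sets with serum was -0.18 in newly transcribed, 0.21 in total and 0.25 in amplified total RNA. It was -0.45 for the response in newly transcribed minus total RNA, -0.53 for newly transcribed minus amplified total RNA, and 0.35 for newly transcribed against amplified total RNA in 1% serum. The p-values measure the spread between arrays that the titles call biological replicates.

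The kinds of RNA differed in the signal of control transcripts along their length. The 3' probe set of GAPDH, a glycolytic enzyme used as a control transcript, stood above the 5' probe set by 2.16 ± 0.65 (log2, SD, n = 8) in newly transcribed and 1.55 ± 0.60 (n = 7) in amplified total RNA, against -0.20 ± 0.11 (n = 8) in total RNA. For the actin control the values were 2.37 ± 0.55, 2.27 ± 0.44 and 0.35 ± 0.17. Whole profiles also split the newly transcribed and amplified arrays into 2 clusters that crossed the serum groups. Cluster 1 held newly transcribed arrays 1 and 4 of both conditions, amplified starved arrays 1 and 3 and amplified treated arrays 1 and 4; cluster 2 held the rest and all total RNA arrays. The mean GAPDH difference was 2.56 in cluster 1 and 1.75 in cluster 2 for newly transcribed RNA, whose ranges overlapped. It was 1.94 and 1.03 for amplified total RNA.

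**Figure D1:**
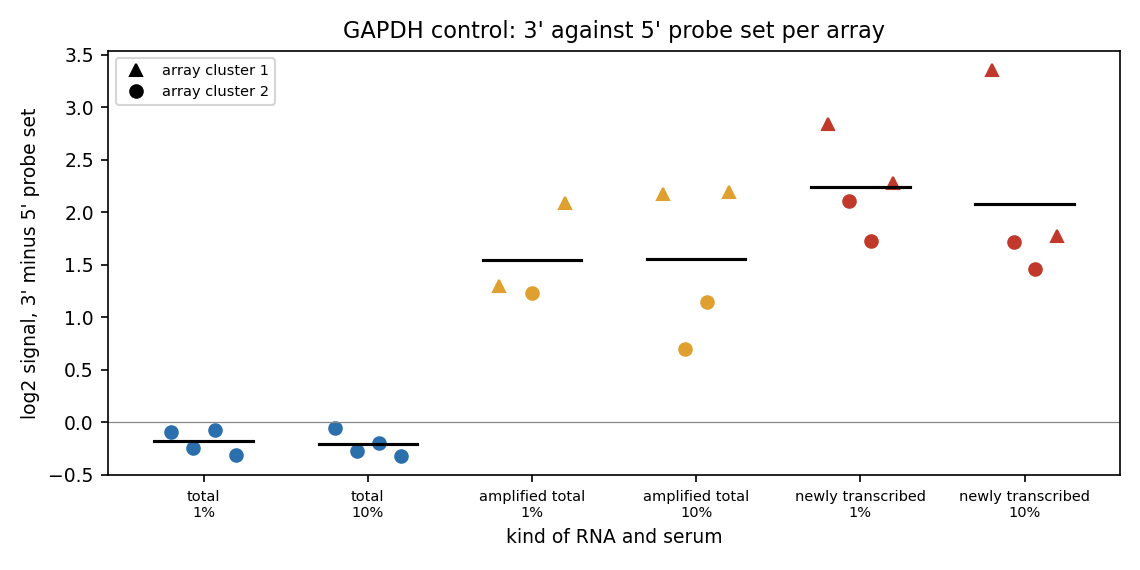
Log2 signal of the GAPDH 3' probe set minus the 5' probe set (y axis) for each array, by kind of RNA and serum percentage (x axis); bars are group means, and triangles and circles mark the 2 array clusters. All 8 total RNA arrays lie below 0, and all amplified and newly transcribed arrays lie above 0.

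In newly transcribed RNA, growth factor and immediate early genes rose within 2 hours of serum. With arrays paired by replicate number (n = 4 pairs), the largest rises among called genes whose groups did not overlap were Fosb, a partner in the AP-1 transcription factor, by 2.56 ± 0.28, Sema7a, a membrane-anchored semaphorin, by 2.40 ± 0.20, and Fgl2 by 2.34 ± 0.30. Next came Has1, a hyaluronan synthase, by 2.17 ± 0.23, Tgfbi, an extracellular protein induced by TGF-beta, by 2.12 ± 0.21, and the nuclear receptor Nr4a1 by 2.03 ± 0.22. Phlda1 and Pkp1 rose by 1.99 ± 0.21 each, and Myc by 1.05 ± 0.11 (adjusted p = 0.026). By the same rule the largest falls were Rab9 (-1.44 ± 0.20), the orphan receptor Nr2f1 (-1.34 ± 0.18), the small matrix proteoglycan Ogn (-1.27 ± 0.15) and Cyp1b1 (-1.25 ± 0.16). Then came Tspyl4 (-1.21 ± 0.17), the repair nuclease Ercc5 (-1.20 ± 0.15), Papss1 (-1.12 ± 0.11) and Rbbp9 (-1.07 ± 0.11). Other probe sets of some of these genes, not called, moved less: Sema7a 0.92, Fgl2 -0.00, Tgfbi -0.00, Pkp1 1.04, Ogn -0.68, Cyp1b1 -0.01, Ercc5 -0.13 and Rbbp9 -0.11. Fos had 1.28 ± 0.27 (adjusted p = 0.073), Egr1 0.90 ± 0.30, Jun -0.00 ± 0.20 and Actb -0.61 ± 0.20, none past the threshold. A second probe set had -0.24 for Fos and -0.12 for Egr1. Limma called 216 probe sets with the pairs (113 higher and 103 lower, 99 of them at least 2-fold), and the groups of 90 did not overlap. Over all probe sets the groups of 3.82% did not overlap, against a chance share of 2.86%. Without the pairs limma called 0, with 800 probe sets at an unadjusted p below 0.05 and a smallest adjusted p of 0.090. The paired count was 25 without pair 1, 1 without pair 2, 0 without pair 3 and 0 without pair 4. It was also 0 with values as deposited and with a pseudocount of 1, and arrays scaled to 1 median gave 118 higher and 178 lower.

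Genes of 5 lists of serum response regulators rose in newly transcribed RNA. Of 23 immediate early transcription factors, which are switched on without new protein synthesis, 8 rose over all probe sets with the pairs and 15 when adjusted over the list alone. Fosl1 rose by 1.78 ± 0.20 and Junb by 1.34 ± 0.17. Among 29 secreted growth factors, cytokines and proteases 10 rose (18 higher and 1 lower when adjusted over the list alone). They included the cytokine Il11 (2.25 ± 0.34) and the activin subunit Inhba (1.91 ± 0.31). Vegfa had 2.02 ± 0.36 (adjusted p = 0.053). Of 20 feedback regulators 5 rose (11 higher and 1 lower over the list alone). Among them were the cytokine signalling inhibitors Socs2 (1.47 ± 0.24), Cish (1.41 ± 0.22) and Socs3 (1.31 ± 0.18) and the mRNA decay factor Zfp36 (1.33 ± 0.16). Of 27 SRF and cytoskeleton targets 4 rose (13 higher and 1 lower over the list alone); Tpm3 rose by 1.08 ± 0.12 (-0.39 in its other probe set, not called), while Cnn1 had 2.06 ± 0.38 and Itga5 1.91 ± 0.41, neither past the threshold. Of 14 SMAD and ID genes 2 rose (7 over the list alone), Tgfbi and the inhibitory Smad7 (0.75 ± 0.11). In the fit without pairs, camera placed these 5 lists up, and 4 held with an estimated correlation: immediate early factors at adjusted p = 0.0067, secreted factors at 0.011, feedback regulators at 0.014 and SMAD and ID genes at 0.031. The SRF list did not hold, with adjusted p = 0.23 with an estimated correlation. With the pairs none of the 5 held, with adjusted p = 0.093 to 0.18 with an estimated correlation.

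Growth arrest and cell cycle genes were on the lower side in newly transcribed RNA. Of 26 growth arrest and starvation genes 4 fell with the pairs (9 over the list alone). Among them were Ccng2, a cyclin of resting cells (-1.52 ± 0.18), and the growth arrest genes Gas1 (-1.46 ± 0.23) and Gas2 (-1.32 ± 0.18; other probe set -0.63). Sesn1 had -1.02 ± 0.27. Of 19 genes of G2 and mitosis 1 fell, the mitotic kinesin Kif20a (-0.76 ± 0.13), and 14 fell when adjusted over the list alone. Top2a (-0.77 ± 0.16) and Aurka (-0.76 ± 0.13) missed the threshold over all probe sets, and 1 of the 19 genes had a positive change. Of 23 genes of G1 and S phase limma called 0 over all probe sets, and 8 fell when adjusted over the list alone. Camera without pairs placed the 3 lists down. In that fit the G1 and S phase list held with an estimated correlation (adjusted p = 0.031). Growth arrest had adjusted p = 0.14 and G2 and mitosis adjusted p = 0.060 with an estimated correlation. With the pairs none of the 3 held with an estimated correlation, with adjusted p = 0.22 for growth arrest, 0.19 for G1 and S phase and 0.17 for G2 and mitosis.

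Each remaining list held at most 3 called genes in newly transcribed RNA. In glycolysis 2 of 11 rose with the pairs, the glucose transporter Slc2a1 (1.28 ± 0.16) and the hexokinase Hk2 (1.14 ± 0.16; -0.09 in its other probe set), and in ribosome biogenesis 1 of 25 rose, the polyamine enzyme Odc1 (0.74 ± 0.11). Camera placed both lists up without the pairs, with adjusted p = 0.40 and adjusted p = 0.12 with an estimated correlation, and the glycolysis median turned from 0.07 to -0.27 with values as deposited (-0.10 relative to all probe sets). Circadian genes went both ways, with Nfil3 higher (1.25 ± 0.18) and Dbp lower (-1.11 ± 0.16) among 14. So did the extracellular matrix list, in which Col6a2 (0.87 ± 0.15) and Col6a1 (0.71 ± 0.11) rose and the proteoglycan Lum fell (-1.38 ± 0.23) among 27. Among 19 mRNA decay regulators 2 rose, Zfp36 and Btg2 (0.90 ± 0.15), and among 17 p53 and stress targets 2 rose, the haem oxygenase Hmox1 (1.11 ± 0.13) and the heat shock gene Hspa1b (0.70 ± 0.11). Gbp2 (0.97 ± 0.15) was the called gene of 17 interferon response genes, and Acta1, the skeletal muscle actin, that of 13 muscle markers (2.10 ± 0.33). Limma called 0 genes of cholesterol and fatty acid synthesis, oxidative phosphorylation, ribosomal proteins and the macrophage, endothelial, epithelial, neural and erythroid markers with the pairs. Camera without pairs passed none of the lists named here after ribosome biogenesis (adjusted p = 0.14 to 0.96); with pairs it placed ribosomal proteins up, with adjusted p = 0.52 with an estimated correlation.

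Total RNA showed the same kinds of regulators rising, and few falls. With pairs (n = 4) and by the same rule, the largest rises were Ptgs2, the inducible prostaglandin synthase (2.61 ± 0.22), the EGF family ligand Ereg (2.42 ± 0.13), the gap junction gene Gjb2 (2.41 ± 0.10) and Nr4a1 (2.40 ± 0.19). Fosb (2.38 ± 0.18) followed, with Errfi1, an inhibitor of EGF receptor signalling (2.36 ± 0.28), Egr2 (2.04 ± 0.15) and Plaur, the urokinase receptor (2.03 ± 0.16). The 3 called falls were Ccng2 (-1.21 ± 0.10), Mab21l2 (-1.20 ± 0.11) and Pnrc2, a factor of mRNA decay (-0.99 ± 0.10). Myc rose by 0.95 ± 0.12 (adjusted p = 0.047), while Fos had 1.71 ± 0.34, Egr1 0.88 ± 0.44, Jun 0.53 ± 0.09 and Actb 0.14 ± 0.18, none past the threshold. Limma called 15 probe sets without pairs (14 higher and 1 lower, the groups of all 15 apart; over all probe sets 2.95% were apart, against a chance share of 2.86%) and 60 with pairs (57 higher and 3 lower). Genes called without pairs included Ptgs2, Nr4a1, Fosb, Egr2, Phlda1 (1.96 ± 0.20), the deadenylase Noct (1.88 ± 0.17), the sulfiredoxin Srxn1 (1.86 ± 0.13), Fgl2 (1.81 ± 0.23) and Pnrc2. Other probe sets, not called in the paired fit, had 0.20 for Ereg, 0.07 for Noct, 0.14 for Srxn1, 0.15 for Fgl2, 0.20 for Fos and 0.10 for Egr1. The count of 15 became 3 without starved array 2, 1 without treated array 2, 1 without starved array 3, 5 without treated array 3, 7 without starved array 4 and 3 without treated array 4, and 2 with values as deposited. The paired count was 8, 10, 0 and 0 without pairs 1, 2, 3 and 4, and 0 with values as deposited and with a pseudocount of 1.

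By list, 7 of 23 immediate early factors rose in total RNA with pairs (17 over the list alone), 7 of 20 feedback regulators (13), 5 of 29 secreted factors (15 higher and 1 lower), 2 of 14 SMAD and ID genes (5) and 1 of 27 SRF targets (3), each second count being adjusted over the list alone. Fosl1 (1.81 ± 0.12), the phosphatase Dusp1 (1.74 ± 0.22), the fibronectin receptor subunit Itga5 (1.83 ± 0.14) and the inhibitor of differentiation Id1 (0.97 ± 0.09) were among them. Slc2a1 (1.33 ± 0.12) and Hk2 (1.16 ± 0.12; other probe set -0.14) rose in the glycolysis list. Camera without pairs placed the 5 regulator lists up, and 4 held with an estimated correlation. These were immediate early factors and feedback regulators at adjusted p = 0.0010, SRF targets at 0.024 and secreted factors at 0.028. SMAD and ID genes had adjusted p = 0.28 with an estimated correlation. With pairs none of these held, with adjusted p = 0.17 to 0.24 with an estimated correlation. Of the growth arrest list 1 of 26 genes fell, Ccng2, with Txnip at -0.95 ± 0.26 (other probe set 0.07) and Gas1 at -0.78 ± 0.15, and of 19 genes of G2 and mitosis limma called 0, with 0 positive changes. Both lists were placed down by camera without pairs, with adjusted p = 0.18 and adjusted p = 0.75 with an estimated correlation; with values as deposited their medians were 0.13 and 0.14, below the 0.21 of all probe sets. Ribosome biogenesis and cholesterol synthesis genes were placed up, with adjusted p = 0.088 and adjusted p = 0.51 with an estimated correlation. Hspa1b (1.13 ± 0.13) and the chaperone Dnajb1 (1.01 ± 0.09) rose among stress targets, and Nfil3 (1.06 ± 0.12; other probe set 0.44) among circadian genes. All 14 macrophage markers had positive changes (median 0.22), with 0 called by limma; camera placed them up, with adjusted p = 0.81 with an estimated correlation.

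Amplified total RNA gave no called probe set for serum. Limma called 0 (3 starved and 4 treated arrays), with 175 probe sets at an unadjusted p below 0.05, and 0 (798 unadjusted) with the array cluster as a block. Among listed genes Nr4a1 was at 2.51 ± 0.31, Ereg at 2.25 ± 0.22 (other probe set 0.06), Ptgs2 at 2.19 ± 0.72, Errfi1 at 1.93 ± 0.42, Fosb at 1.82 ± 0.38, Ccng2 at -1.31 ± 0.64 and Gas1 at -1.04 ± 0.59. As groups, immediate early factors (median 0.72, 20 of 23 positive), feedback regulators (0.57, 16 of 20) and secreted factors (0.49, 25 of 29) were higher by camera. They held with an estimated correlation at adjusted p = 0.0036, 0.0046 and 0.0036. In these lists limma called 0 genes over all probe sets and 2, 3 and 1 when adjusted over the list alone. Camera also placed SRF targets (adjusted p = 0.24 with an estimated correlation) and SMAD and ID genes (adjusted p = 0.087 with an estimated correlation) up, as well as circadian genes (adjusted p = 0.087 with an estimated correlation), glycolysis (adjusted p = 0.38 with an estimated correlation) and macrophage markers (adjusted p = 0.59 with an estimated correlation). It placed growth arrest and G2 and mitosis genes down, both with adjusted p = 0.33 with an estimated correlation, and with values as deposited their medians were 0.22 and 0.12, below the 0.25 of all probe sets.

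The responses of newly transcribed and total RNA overlapped. Of 113 probe sets higher in newly transcribed and 57 higher in total RNA with pairs, 33 were in both, against 0.52 in independent lists of these sizes (Fisher's exact test, p = 1.6e-54). All 3 lower in total RNA were among the 103 lower in newly transcribed RNA (Fisher's exact test, p = 5.5e-07). Both p-values take probe sets as independent, which they are not, so they are too small and do not measure the spread between arrays. The 113 had a median of 1.08 in newly transcribed and 0.75 in total RNA, with the same sign for 106. The 103 had medians of -0.90 and -0.28, with the same sign for 95. These 2 sets were picked on newly transcribed RNA, so their medians there are inflated. Across probe sets, which are not independent replicates, the responses correlated with r = 0.47 (Spearman 0.31) between newly transcribed and total, 0.43 between newly transcribed and amplified total, and 0.38 between total and amplified total RNA. The second value was 0.19 without amplified starved array 3, 0.24 without newly transcribed treated array 3, 0.25 without newly transcribed treated array 2 and 0.28 without newly transcribed starved array 4, and the third was 0.23 without amplified starved array 2. With the array cluster as a block in amplified RNA they were 0.37 and 0.43, so their order is not settled. Newly transcribed and amplified treated arrays of the same number deviated together, as did starved arrays 1 and 2 (0.37 and 0.68) but not 3 (-0.39), which can correlate their responses without a serum effect. With responses from 2 numbers in each kind, the correlation of newly transcribed and amplified RNA averaged 0.30 (0.01 to 0.58) from the same and 0.16 (-0.13 to 0.37) from other numbers. These ranges overlap, so the part due to shared numbers is not settled. Amplified RNA has no starved array 4, and its starved array 3 did not match treated array 3 (-0.47), so responses with these numbers are not matched. The correlation of total and amplified RNA averaged 0.25 (0.14 to 0.31) and 0.14 (0.07 to 0.24), and that of newly transcribed and total RNA 0.36 (0.28 to 0.45) and 0.32 (0.22 to 0.41). With values as deposited the 3 correlations were 0.13, 0.057 and 0.61.

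**Figure D2:**
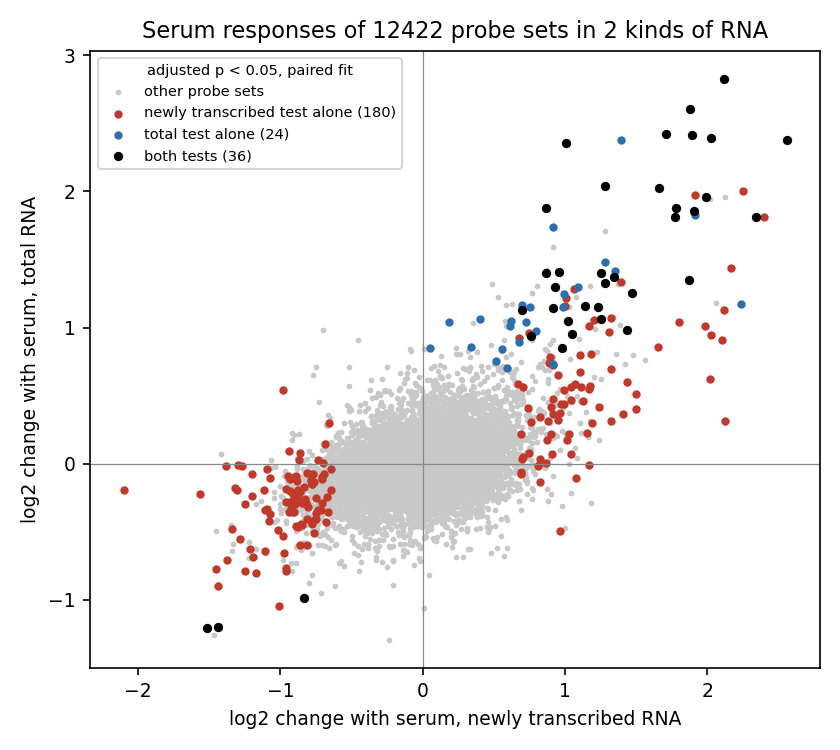
Log2 change with serum in newly transcribed RNA (x axis) against that in total RNA (y axis) for 12422 probe sets, coloured by the paired test they passed at an adjusted p below 0.05. Both tests called 36 probe sets, the newly transcribed test alone 180 and the total test alone 24.

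A test of the difference between the responses of newly transcribed and total RNA called 0 probe sets with limma, with 299 at an unadjusted p below 0.05, and 0 with pairs kept within each kind (1343 unadjusted, smallest adjusted p 0.16). Listed genes had wide intervals in the paired test. The tropomyosin Tpm3 had 1.18 more in newly transcribed RNA (95% interval 0.76 to 1.61, adjusted p = 0.16) and Tgfbi 0.99 (0.24 to 1.74). Errfi1 had -1.35 (-2.09 to -0.61), Ereg -0.71 (-1.09 to -0.33), Egr2 -0.76 (-1.25 to -0.27), Gas2 -1.14 (-1.64 to -0.63), Lum -1.36 (-1.95 to -0.77) and Gas1 -0.68 (-1.34 to -0.02). Other probe sets had -0.43 for Tpm3, -0.18 for Tgfbi, -0.71 for Errfi1, 0.08 for Ereg and -0.55 for Gas2. None of these differences passed the adjustment, so an effect called in one kind of RNA is not shown to be absent in the other. Against amplified total RNA the difference also gave 0 calls (201 unadjusted; with the array cluster as a block 0 and 1083). Tpm3 was at 1.08 (0.45 to 1.71), the orphan receptor Nr4a2 at 1.20 (0.33 to 2.06) and the desaturase Scd2 at -1.05 (-1.77 to -0.32), with 0.44, 0.44 and 0.06 in their other probe sets. On scarce transcripts, 15 of the 113 probe sets higher in newly transcribed RNA with pairs (13.3%) and 29 of the 103 lower (28.2%) lay below the median level of all probe sets in total RNA, as did 3 of the 57 higher in total RNA (5.26%). The differences of these shares were not tested.

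**Figure D3:**
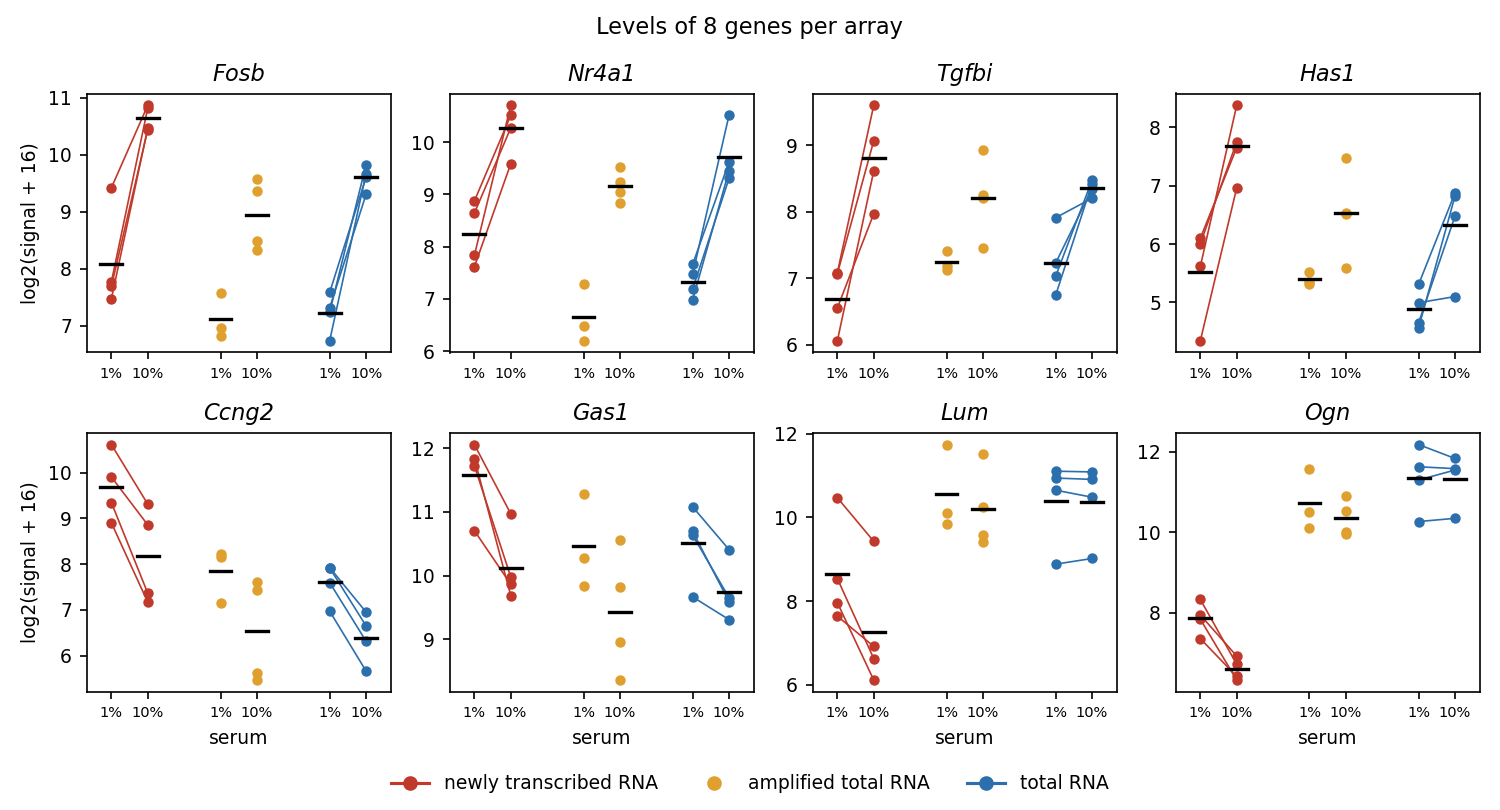
Log2(signal + 16) of 8 genes (y axis) on each array at 1% and 10% serum (x axis), by kind of RNA; points are arrays, black bars group means, and lines join same-numbered arrays where the numbers paired. Fosb, Nr4a1, Tgfbi and Has1 have higher and Ccng2 and Gas1 lower means at 10% serum in the 3 kinds of RNA, and Lum and Ogn are at lower levels in newly transcribed RNA than in either other kind.

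Newly transcribed RNA was compared with total RNA that the titles call amplified, in each serum condition. The turnover, length and uridine content of transcripts were not analysed. An excess or deficit, of a gene or of a list, is thus not shown to come from recent transcription. In 1% serum the largest excesses in newly transcribed RNA were Tiparp (2.64 ± 0.57), a poly-ADP-ribose polymerase induced by aryl hydrocarbons, and the transcription factor Klf2 (2.50 ± 0.43). They were followed by the kinases Plk2 (2.24 ± 0.43) and Map3k8 (2.16 ± 0.57), Tsr1 (2.15 ± 0.42), Ppp1r15b (2.12 ± 0.58), Camsap1 (2.08 ± 0.43) and Nup62 (2.08 ± 0.45). The largest deficits were the histone gene H3c14 (-3.44 ± 0.67), the lysosomal hydrolase Ggh (-3.36 ± 0.32) and the respiratory chain subunits Ndufa3 (-3.09 ± 0.27) and Uqcr11 (-2.84 ± 0.51). Others were Apoe, an apolipoprotein (-2.89 ± 0.71), Ogn (-2.86 ± 0.35), Cpq (-2.73 ± 0.40) and the cell cycle inhibitor Cdkn1c (-2.71 ± 0.44). Other probe sets, not called, had -0.43 for Map3k8 and -0.23 for Apoe. In 10% serum the excesses were led by Foxc2 (2.12 ± 0.39), Sema7a (2.09 ± 0.27), Smad1 (2.01 ± 0.52), Nup62 (1.93 ± 0.42), Sox11 (1.91 ± 0.54), Dnajb4 (1.88 ± 0.28), Klf2 (1.86 ± 0.40) and Rgs16 (1.83 ± 0.50). The deficits were led by Ogn (-3.76 ± 0.32), Itm2a (-3.67 ± 0.49), H3c14 (-3.54 ± 0.62), Ggh (-3.52 ± 0.30), Apoe (-3.52 ± 0.66), the proteoglycan Dcn (-3.16 ± 0.53), Agtr2 (-3.06 ± 0.71) and Cpxm2 (-3.04 ± 0.20). Other probe sets, not called, had 1.12 for Foxc2, 1.05 for Sema7a, 1.85 for Smad1, 1.65 for Rgs16, -0.15 for Apoe and 0.14 for Agtr2. Limma called 715 probe sets in 1% serum (301 higher and 414 lower, the groups of 710 apart) and 902 in 10% serum (323 and 579, 840 apart). Over all probe sets the groups of 16.6% and 11.1% were apart, against chance shares of 5.71% and 2.86%. With the replicate number as a block on all 15 arrays, starved ones included, the 10% count was 2328 (1119 and 1209). Treated arrays alone with pairs gave 2626. The counts in 1% serum were 345 without amplified starved array 2, 462 without amplified starved array 1, 422 without newly transcribed starved array 3 and 460 without newly transcribed starved array 2. The count in 10% serum was 563 without amplified treated array 2. Within array cluster 1 the counts were 0 and 0. Within cluster 2 the count in 10% serum was 2862, on treated arrays 2 and 3 of each kind. For 1% serum no count is given, as array 2 was the only amplified starved array in cluster 2. With the cluster as a block the counts were 2301 and 2556. The clusters were found on the same values, so p-values with that block are too small. With values as deposited both counts were 0.

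By list, immediate early, feedback, secreted and circadian genes were higher, and oxidative phosphorylation and ribosomal protein genes lower, in newly transcribed RNA. In 1% and 10% serum, 5 and 6 of 23 immediate early factors were higher (12 higher and 1 lower, and 13 higher, over the list alone), such as Jun (1.77 ± 0.21 in 1%) and Atf3 (1.63 ± 0.27 in 1%, and -0.02 in another of its 3 probe sets). So were 3 and 5 of 20 feedback regulators (8, and 11 higher and 1 lower, over the list alone). Also higher were 4 and 3 of 29 secreted factors (7 and 5) and 3 and 3 of 14 circadian genes (6 higher and 1 lower, and 5), such as Bhlhe40 (1.91 ± 0.26 and 1.57 ± 0.24), a repressor of the clock. Of 30 genes of oxidative phosphorylation 16 and 15 were lower (19 and 19 over the list alone), with medians of -1.30 and -1.23. Examples were Uqcrh (-2.56 ± 0.36 and -2.12 ± 0.33), Atp5o (-2.43 ± 0.36 and -2.30 ± 0.34) and Ndufa2 (-2.27 ± 0.31 and -2.07 ± 0.29). Of 16 ribosomal proteins 2 and 2 were lower (10 and 8 over the list alone), with medians of -0.80 and -0.82. These 6 lists held with an estimated correlation in both conditions, at adjusted p = 0.00045 to 0.036. Of 27 extracellular matrix genes 5 and 7 were lower, among them Dcn (-2.36 ± 0.58 and -3.16 ± 0.53), but with adjusted p = 0.075 and adjusted p = 0.10 with an estimated correlation. Macrophage markers, listed as signs of other cells, were lower in 2 and 2 of 14, with a median of -0.85 in 1% serum (0.13 with values as deposited, -0.22 relative to all probe sets). Adgre1 was among them (-1.69 ± 0.34 and -1.57 ± 0.31; -0.05 and 0.03 in its other probe set), and the list had adjusted p = 0.34 and adjusted p = 0.31 with an estimated correlation. Ribosome biogenesis genes were higher in 10% serum in 4 of 25, such as Rcl1 (1.23 ± 0.21), with adjusted p = 0.028 with an estimated correlation. SMAD and ID genes were higher in 3 of 14, such as Tgif1 (1.48 ± 0.25), with adjusted p = 0.036 with an estimated correlation. Among mRNA decay regulators 2 of 19 were higher in each condition, with adjusted p = 0.23 and adjusted p = 0.11 with an estimated correlation.

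**Figure D4:**
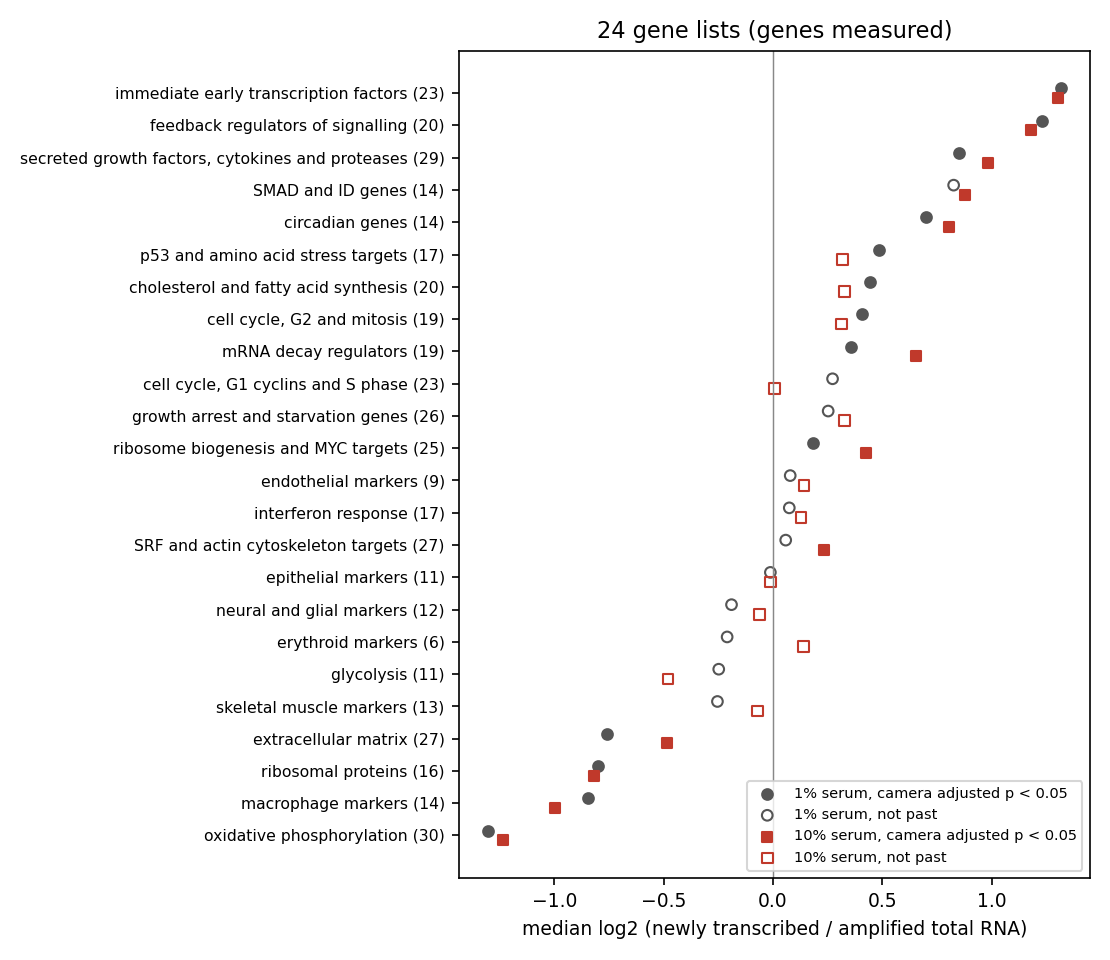
Median log2 ratio of newly transcribed to amplified total RNA (x axis) for each of 24 gene lists (y axis, genes measured in brackets) in 1% serum (grey circles) and 10% serum (red squares), with filled symbols where camera passed with its preset correlation. Oxidative phosphorylation has the lowest medians (-1.30 and -1.23) and immediate early transcription factors the highest (1.32 and 1.30).

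Amplified and unamplified total RNA, told apart by their titles alone, were compared to see how their signals differ. The largest excesses in amplified RNA were the G protein subunit Gnb5 (2.49 ± 0.46), the nuclear pore gene Nup54 (2.41 ± 0.42), Zmynd8 (2.38 ± 0.39) and Smarcd2 (2.34 ± 0.14). They included the mitochondrial genes Mrps25 (2.17 ± 0.17), Lonp1 (2.15 ± 0.28) and Fdx1 (2.14 ± 0.24), and Osbpl5 (2.15 ± 0.30). The largest deficits were the metalloproteinase inhibitor Timp2 (-3.27 ± 0.51), the transcription factor Nfix (-3.25 ± 0.33), Exoc4 (-2.49 ± 0.33) and Arf3 (-2.37 ± 0.25). Next were Tnfaip1 (-2.34 ± 0.20), Grb10 (-2.34 ± 0.26), Mrc2 (-2.31 ± 0.33) and the deubiquitinase Usp22 (-2.27 ± 0.29). Probe sets of 1 gene often differed here: the other extreme was -0.68 for Smarcd2, 0.44 for Mrps25, -0.14 for Lonp1, 0.10 for Fdx1, 0.23 for Timp2, -1.82 for Nfix, -0.61 for Arf3 and -0.33 for Tnfaip1. The 3 probe sets of Grb10 ran from -3.57 to 0.04. Limma called 2338 probe sets on 15 arrays (1221 higher and 1117 lower), 975 of them at least 2-fold. Of the lists, camera placed SRF targets down (7 of 27 lower and 1 higher), with adjusted p = 0.56 with an estimated correlation. Oxidative phosphorylation had 10 of 30 higher and 1 lower (median 0.18) and ribosomal proteins 1 of 16 higher and 2 lower, neither list past camera. Scaling to 1 median gave 1584 higher and 750 lower, and values as deposited gave 13 higher and 251 lower.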

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

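Of the tests below, those of culture differences and of unequal cluster numbers were chosen after the results were seen. So were the splits that part newly transcribed and amplified pairs. The tests of an amplification effect used the array clusters, which were found in the same data. The tests of selection and of dilution used probe sets called with pairs, and the pairing also came from the data. These tests of explanations were thus not fixed independently of the data. The counts of splits without pairs were not chosen after the results were seen.

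The newly transcribed and amplified arrays fell into 2 clusters that crossed the serum groups. For a different strength of the amplification, the cluster 1 minus cluster 2 difference of newly transcribed arrays was set against amplified cluster 2 arrays minus total RNA. Across probe sets they correlated at -0.25 (-0.27 to -0.23 without each array). Cluster 2 enters both sides with opposite signs, and its same-numbered arrays of both kinds deviated together (0.68 for starved 2, 0.73 and 0.71 for treated 2 and 3). That alone pushes the correlation below 0, so the test cannot decide. The mean 3' minus 5' signal was higher in cluster 1, though not on every array, so a different strength of the amplification stays open. GAPDH means in newly transcribed RNA were 2.56 (1.78 to 3.36) in cluster 1 and 1.75 (1.46 to 2.11) in cluster 2, and these ranges overlap. In amplified RNA they were 1.94 (1.30 to 2.19) and 1.03 (0.70 to 1.23). Actin means in clusters 1 and 2 were 2.75 and 1.98 in newly transcribed RNA. In amplified RNA they were 2.38 (SD 0.30) and 2.12 (SD 0.62). A difference between cultures could also show in total RNA; the correlation there was 0.12 (0.07 to 0.15), above the 0.061 of the other splits but small, so this explanation stays open. The labels give no batch, and no biological explanation was tested.

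The 103 probe sets lower in newly transcribed RNA with pairs had medians of -0.90 there and -0.28 in total RNA. Selection of extreme values alone was argued against: for 103 probe sets picked on pairs 2 and 3, the held-out pairs 1 and 4 had medians of -0.56 and -0.36 against -0.21 in total RNA, a mean ratio of 2.22 (1.74 and 2.69). A candidate explanation is dilution by RNA made before the labelling, under which genes more enriched in newly transcribed RNA fall more in total RNA. Across the 103 probe sets the Spearman correlation was -0.51 (bootstrap interval over probe sets -0.65 to -0.34). That interval does not measure the spread between arrays. Enrichment was newly transcribed minus amplified total RNA, averaged over both serum conditions. A fall with serum that total and amplified RNA share thus raises the enrichment by itself. This can push the correlation below 0 without dilution, so the test cannot decide. The explanation was found and tested on the same data. The difference of the responses passed for 0 single probe sets with limma (1343 at an unadjusted p below 0.05 with pairs).

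Oxidative phosphorylation genes were lower in newly transcribed than in amplified total RNA. For a stronger amplification effect in newly transcribed RNA, amplified cluster 1 arrays were taken as a stand-in. The median of these genes in amplified cluster 1 minus total RNA was 0.064 (0.058 to 0.146 without each array). It was -1.28 in newly transcribed minus amplified arrays of cluster 2. Amplified RNA of cluster 1 thus showed no deficit of these genes. The amplification of newly transcribed RNA itself was not measured, so its effect stays open. Unequal numbers of both clusters were argued against for starved arrays, whose median was -1.36 with the cluster as a block. The treated groups of both kinds held equal numbers of both clusters. The block thus could not change their median of -1.23, and their deficit was present without unequal numbers. The turnover, length and uridine content of these transcripts were not analysed here.

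Other splits of the arrays were counted for each test. The real split alone reached its count for newly transcribed against amplified total RNA in 1% serum (1 of 35 splits, 715 probe sets against 80 in the highest other). The same held for amplified against total RNA (1 of 100, 2338 against 650). These are the smallest shares such splits can give, and they were not adjusted for the number of tests. Chance is thus less likely there but not excluded. Over all splits without pairs another split gave more calls for newly transcribed against amplified total RNA in 10% serum (2 of 35, 902 against 1760). So it did for serum in total RNA (2 of 35, 15 against 138), and chance stays open for both. The split with 1760 followed the clusters and parted 0 of the 4 pairs of newly transcribed and amplified arrays, and 2556 were called with the cluster as a block. Where the real count was 0, every split is as large, so the count of splits says nothing about chance. This holds for the unpaired serum tests in newly transcribed (35 of 35; highest other 3333) and amplified total RNA (35 of 35; 3021), where the highest split followed the clusters and points to a structure of the samples. It also holds for the differences of responses (100 of 100 each; 1353 for amplified and 2500 for total RNA). With pairs, 8 splits part all pairs (1 of 8 as large in each), too few for a share under 0.05. The real counts were 216 and 60 for serum in newly transcribed and total RNA and 2328 for newly transcribed against amplified total RNA in 10% serum, and the highest other was 0 in each.

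By an outlier test 2 of 15 groups of array measures and 18 of 375 groups over 75 named genes (4.8%) held an array far from the others, and chance gives about 1 in 20. The GAPDH 3' minus 5' value of newly transcribed treated array 1 was 3.36 (others 1.46 to 1.78), and the actin value of amplified treated array 2 was 1.40 (2.41 to 2.58). Among newly transcribed arrays, log2 levels apart from the rest were Fosb in starved 2 at 9.42 (7.47 to 7.77), and Ggh in starved 1 at 6.44 (5.45 to 5.54). Further ones were Plk2 in treated 4 at 10.15 (11.46 to 11.62), Papss1 in treated 4 at 5.67 (6.66 to 6.72) and Foxc2 in treated 1 at 9.44 (10.48 to 10.58). Starved array 4 stood apart for Cpq at 6.27 (5.36 to 5.50), Nup54 at 11.47 (9.68 to 9.87), Nfix at 8.83 (5.97 to 6.23) and Usp22 at 4.66 (5.50 to 5.57). In total RNA these were Plk2 at 11.18 (10.40 to 10.46) and Timp2 at 9.40 (11.38 to 11.50) in treated 1. Others were Actb at 9.40 (8.41 to 8.55), Uqcr11 at 9.25 (8.34 to 8.39) and Elob at 11.51 (11.22 to 11.25) in treated 2, Map3k8 at 4.66 (others at most 4.27) in starved 4 and Nfix at 11.22 (10.55 to 10.57) in starved 3. In amplified total RNA they were Jun at 8.62 (8.11 to 8.18) in treated 4 and Exoc4 at 4.76 (6.17 to 6.46) in treated 1.

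By camera the serum response in newly transcribed minus total RNA, with pairs, differed for SRF targets (median 0.22), ribosomal proteins (0.25), oxidative phosphorylation (0.13), feedback regulators (-0.40), G2 and mitosis (-0.26) and G1 and S phase (-0.24), with adjusted p = 0.30 to 0.43 with an estimated correlation. Against amplified total RNA, with the array cluster as a block, SRF targets differed (median 0.29), with adjusted p = 0.53 with an estimated correlation.

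The GAPDH 3' control probe set with the suffix st was outside all tests. It had a mean log2 signal of 6.38 ± 0.75 (SD, n = 8) in newly transcribed and 6.58 ± 0.70 (n = 7) in amplified total RNA. In total RNA it had 5.16 ± 0.53 (n = 8). The ranges overlapped, at 5.76 to 7.56, 5.81 to 7.67 and 4.30 to 5.95. Newly transcribed and amplified arrays numbered 1 had the highest values, from 7.29 to 7.67.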

How the results depend on the processing

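Fits by array cluster, treated arrays alone, those without both amplified arrays numbered 1, blocks within a kind of RNA or with clusters, other scalings of list medians and all alternatives that keep the pairs, except the paired fits themselves, were chosen after the data were seen. The cause of the shifts below was not tested. Of values for named genes under alternatives, 7028 kept direction and side of the threshold, 437 passed it newly, 474 no longer did and 43 changed sign, none of them past the threshold; of list medians 118 were the same, 10 moved and 4 turned. The 4, with values as deposited, were glycolysis in newly transcribed RNA (-0.27), growth arrest (0.13) and G2 and mitosis (0.14) in total RNA, and macrophage markers in newly transcribed against amplified total RNA in 1% serum (0.13). This tally of lists leaves out the serum response in amplified total RNA. There growth arrest and G2 and mitosis, placed down by camera, also had positive medians with values as deposited. Dim arrays limit what can be seen, with a lowest median raw signal of 7.3.

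The unpaired count in newly transcribed RNA was 216 with pairs, 30 with all 23 arrays in 1 fit, 14 with array weights, 3 with a pseudocount of 64, 1301 in cluster 2 alone with pairs, and 0 to 1 without each array. In total RNA it was 2 with values as deposited, 60 with pairs, 23 with array weights, 7 with a pseudocount of 1, 24 and 24 without the dimmest 25% and 50%, and 1 to 19 without each array. In amplified total RNA it was 3 with all arrays in 1 fit and 0 with a replicate block; its difference from newly transcribed RNA was 0 throughout, and that of newly transcribed minus total RNA was 1 with array weights.

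Newly transcribed against amplified total RNA gave, in 1% and 10% serum, 0 and 0 with values as deposited, 1912 and 2328 with a replicate block, 1174 and 1413 with all arrays in 1 fit, 1169 and 1695 with array weights, and 401 and 596 with a pseudocount of 1. They were 1567 and 1975 with the culture as a random block, 3406 and 2964 against total RNA, 2301 and 2556 with a cluster block, and 0 and 0 in cluster 1. They were 2434 and 2862 in cluster 2, and 345 to 765 and 563 to 972 without each array. Treated arrays alone with pairs gave 2626. Amplified against total RNA gave 264 with values as deposited and 975 with a limit of 2-fold. Without both amplified arrays numbered 1 these 3 tests gave 626, 1107 and 1956. Numbers did not pair the amplified starved and treated arrays (correlations of 0.69, 0.76 and -0.47), but starved array 3 was closest to treated array 4 (0.79).

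With pairs kept, the count in newly transcribed RNA was 621 and 718 without the dimmest 25% and 50%, 0 with values as deposited, 0 with a pseudocount of 1, 124 with 64, 1052 with array weights, 99 with a limit of 2-fold and 0 to 25 without each pair. In total RNA it was 128 without the dimmest 50%, 0 with values as deposited, 0 with a pseudocount of 1, 100 with trend and robust variance and 0 to 10 without each pair.

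The correlation of responses was 0.13 with values as deposited for newly transcribed and total RNA (0.38 to 0.48 without each array). For newly transcribed and amplified total RNA it was 0.56 in the brightest 50%, 0.057 as deposited and 0.19 to 0.52 without each array; for total and amplified total RNA it was 0.49, 0.61 and 0.23 to 0.41. Without pairs, lists past camera with an estimated correlation numbered 5, 4 and 3 in newly transcribed, total and amplified total RNA, and 0 for newly transcribed minus total RNA. They numbered 6 for newly transcribed against amplified total RNA in 1% serum and 0 for amplified against total RNA. With the preset correlation and the mean of all probe sets per gene, 5 lists passed for newly transcribed minus total RNA.

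Changed signs with values as deposited were -0.023 for Nr1d1 in newly transcribed RNA, and 0.109 for Mcm7, 0.206 for Cdk4 and 0.064 for Ccna2 in total RNA. In amplified total RNA they were 0.128 for Mcm4, 0.234 for Pcna, 0.065 for E2f1, 0.0053 for Plk1, 0.184 for Lamc1, 0.173 for Fn1, 0.342 for Tk1, 0.219 for Mcm2 and 0.218 for Pgk1. Jun in newly transcribed RNA had 0.024 with arrays scaled to 1 median, and 0.379 in cluster 1, where Nr1d1 had -0.062. With array weights Fbln1 had -0.069 in total RNA and Tk1 had 0.022 in amplified total RNA. Against total in place of amplified RNA in 1% serum Ier3 had -0.170 and Lamb1 had 0.181. Without each array the ranges were -0.114 to 0.094 for Jun and -1.774 to 0.368 for Actb in newly transcribed RNA. In total RNA they were -0.139 to 0.436 for Fbln1, -0.0085 to 0.404 for Pfkp and -0.085 to 0.266 for Actb. In amplified total RNA they were -0.303 to 1.083 for Rrm2, -0.755 to 0.130 for Fn1, -0.350 to 0.934 for Col6a2, -0.101 to 0.877 for Pkm, -0.029 to 0.719 for Pfkp, -2.167 to 0.087 for Actb, -0.399 to 0.077 for Tk1 and -0.20 to 0.69 for Eln. For C1qb in newly transcribed against amplified total RNA in 1% serum the range was -1.701 to 0.018.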

Other observations

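The family tests here were all chosen after the results were seen, on families picked by name.

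Genes named Zfp, mostly zinc finger proteins, were higher in newly transcribed than in amplified total RNA. In 1% serum 80 of 89 had a positive difference (median 0.74, 13 called) and in 10% serum 81 of 89 did (median 0.65, 11 called), with camera adjusted p = 9.1e-13 and 1.1e-09 over 3 families, and adjusted p = 0.00042 and 0.0014 with an estimated correlation. Glutathione transferase genes, which detoxify reactive compounds, had a negative difference in 18 of 18 in both conditions, with 6 called in each and some near 0, such as Gsta1 at -0.013 and -0.012 (medians -1.18 and -1.44), with adjusted p = 3.4e-06 and 9.4e-09, and adjusted p = 0.017 and 0.0048 with an estimated correlation. In amplified against total RNA the adjusted p were 0.76 and 0.50. The turnover, length and uridine content of the transcripts of both families were not analysed.

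With serum, 66 of 89 Zfp genes had a negative change in newly transcribed RNA with pairs (median -0.18, 3 lower and 1 higher called), with adjusted p = 0.0013, and adjusted p = 0.078 with an estimated correlation. The 20 histone genes measured were not lower together in both conditions against amplified total RNA, with adjusted p = 0.068 in 1% and 0.026 in 10% serum, and adjusted p = 0.11 and 0.059 with an estimated correlation.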
